A study of Mus musculus with 2 samples.

How the data were processed

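Heart RNA was sequenced from 4-day-old male B6CASTF1/J mice, the F1 offspring of a cross between C57BL/6J and CAST/EiJ. The labels list 2 biological replicates from animals with different numbers and different sample records but the same donor record. They were treated as 2 animals, and if both came from 1, the SD and the coefficient of variation would measure technical error alone. Both belong to 1 group, so the design holds no contrast between conditions. Per the labels, each library was a stranded total RNA library with ribosomal RNA reduced, made from 300 ng of RNA with ERCC spike-ins added.

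Per the file headers, the deposited gene and transcript tables hold expected counts and TPM (transcript abundance scaled to the library) in columns named as RSEM writes them. Notes deposited beside the files give the build mm10 and the annotation GENCODE M21, and state that these tables came from an alignment to transcripts. A further deposited transcript table per library holds estimated counts and TPM in columns named as kallisto writes them, made from 1 read file against an index of the same build and annotation. The aligner, the tool versions and their settings were not given in the sources used here. The authors' TPM was computed over all rows, spike-ins included. In the first tables the effective length of a transcript was its length less 99 nt, and in the second it was shorter by 342 nt in replicate 1 and 352 nt in replicate 2. Short RNAs carry high TPM in the first tables and few counts in the second, and the cause was not tested. The gene tables also give bounds of an interval of TPM whose level is not stated. Some of these intervals do not hold the TPM itself. For most of the 25 nuclear protein-coding genes with the highest mean TPM, it lay above the upper bound in both replicates. Myl2 in replicate 1 had a TPM of 8793 and bounds of 8497 and 8615. The authors' tables list 55536 mouse genes, and all 55536 identifiers were found in the annotation used here.

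Total expected counts were 31698880 in replicate 1 and 35939759 in replicate 2. The 96 spike-ins, a phiX row with 0 counts and 26248 numbered short rows that name no gene were left out of library sizes. The numbered rows held 2 counts in replicate 1 and 4 in replicate 2, a share of 6.31e-06% and 1.11e-05%. Where a count was 0, the floor was set at 3 counts, which is 0.0952 CPM in replicate 1 and 0.0839 in replicate 2. Intervals on counts are exact binomial intervals at the 95% level, and floors and intervals cover counting error only, since reads copied by PCR are not independent molecules.

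Expected counts were rounded to whole numbers before count-based steps. Scaling used TMM and filtering used filterByExpr in edgeR 4.0.16 under R 4.3.3, with a prior count of 2 for log values, and the spread was taken as edgeR's common biological coefficient of variation. DESeq2 1.42.0 was an alternative. Levels are TPM, a gene was called expressed at a TPM of at least 1 in both libraries, and log ratios of TPM used a pseudocount of 0.1. Other steps used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Biopython 1.88.

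No test across samples was run. With 2 hearts the smallest two-sided p of an exact sign-flip test is 0.5. Differences between the hearts are log2 ratios of replicate 2 over replicate 1 and describe these libraries alone. A gene list was described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. Lists with at least 5 filtered members were used, which left 42 of 48. Genes of a list can be regulated together, and random lists do not carry that, so a percentile past 2.5 or 97.5 is a description and no p-value.

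The 48 gene lists, 30 gene pairs and 30 genes examined for transcripts were fixed before the data were examined, as were the rule for named genes and the alternatives, except for 4 alternatives identified as later choices. Of 621 listed genes, 617 were matched by symbol and 2 by an older symbol. Symbols shared by several identifiers were resolved to the protein-coding one. Named genes were the 25 nuclear protein-coding genes and the 10 other nuclear genes with the highest mean TPM, up to 4 leading members of each list and members under a TPM of 1, all pairs, the 12 protein-coding genes with the largest log2 ratio in each direction among those with a mean of at least 100 counts, the 10 genes with a mean TPM of at least 10 that differed most between the quantifications, and the leading transcripts. Not every gene that meets the rule is printed, and a few are not reported here. Rag1, Xist and genes in the closing section's account of imprinted, clock and nuclear RNAs were named after their values were seen where the rule does not reach them.

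The count step was tested on simulated data drawn from the real means of the filtered genes, with 200 genes changed. After filtering the simulated counts, 16019 genes were left. A simulated coefficient of variation of 15% was recovered as 16.7%. A true log2 ratio of 1, given to only part of the 200 changed genes, was recovered as a median of 1.03. The list step was tested on lists drawn from the 16271 filtered genes. Of 100 random lists of 12 genes, 7% lay past the percentile limits, and of 20 lists of 10 genes shifted by 0.5 on the log2 scale, 95% lay above the upper limit.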

Results

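Total RNA from the hearts of 4-day-old male mice was measured in 2 libraries, 1 per animal, with 31512596 expected counts on mouse genes in replicate 1 and 35744013 in replicate 2. The labels state no question beyond describing this tissue, so the values below describe which genes the newborn heart expressed and how far the 2 hearts differed. Levels are mean TPM ± SD with n = 2 unless stated, and coordinates are those of mm10 with GENCODE M21. Such an SD rests on 2 values and is itself imprecise. Where the mean TPM by the second quantification of the same libraries differed by over 1.5 times, it follows in brackets after the word second.

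At a TPM of at least 1 in both hearts, 13243 genes were expressed, of which 11867 were protein-coding. Transcripts of contractile proteins led the nuclear protein-coding genes. Myl2, the ventricular regulatory light chain (chromosome 5, 122100951 to 122113472), reached 8469 ± 459 TPM (second 20931). Myh6, the fast cardiac myosin heavy chain (chromosome 14, 54941921 to 54966927), reached 7935 ± 1029, and cardiac actin Actc1 reached 7443 ± 680. Myl3 (4183 ± 89.4; second 7369), Tpm1 (3455 ± 74.8) and Tnnt2 (3352 ± 448; second 5293) followed, with the oxygen-binding protein Mb at 3186 ± 220 and the fatty acid carrier Fabp3 at 2975 ± 130 (second 4813). The calcium pump Atp2a2 stood at 2374 ± 84.5 and its inhibitor Pln at 1499 ± 18.2 (second 2382). Ttn, which encodes the giant spring protein titin, had 1195 ± 297 TPM but 1337638 and 1087803 expected counts in the 2 libraries, because of its length.

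All 26 sarcomere genes and all 16 calcium handling genes were expressed. The sarcomere list took 4.89% ± 0.290 of all mouse-gene TPM, 9.57% of expected counts and 7.81% of TPM by the second quantification. Of the 20 cardiac transcription factors, 18 were expressed, led by Tbx20 at 136 ± 30.9, Mef2a at 104 ± 4.96 and Gata4 at 95.3 ± 5.16. Hand1 and Isl1, which act in the embryonic heart fields, had mean TPM of 0.36 and 0.14 (second 0.224 for Isl1). Among ion channels and junction proteins, 20 of 22 were expressed, with the gap junction protein Gja1 at 343 ± 23.2, and Kcnd3 had a mean TPM of 0.49.

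Energy metabolism genes were expressed with 1 exception. All 24 nuclear genes of oxidative phosphorylation, all 26 of fatty acid oxidation and all 22 of glycolysis passed a TPM of 1 in both hearts, as did 5 of 6 genes of ketone use. Atp5b, the catalytic subunit of ATP synthase, reached 2917 ± 200, and the beta-oxidation enzyme Acaa2 reached 609 ± 7.34. Gapdh stood at 1628 ± 301 (second 4635) and Aldoa at 1104 ± 199. The nuclear oxidative phosphorylation list took 1.64% ± 0.124 of mouse-gene TPM. The 13 protein-coding genes of the mitochondrial genome took 7.66% ± 0.146, led by mt-Co1 at 20992 ± 517. That share leaves out reads given to nuclear copies of the same genes, so it is uncertain. Gm28661 (chromosome 1, 24614885 to 24615565), a copy of mt-Co2, had 17406 ± 485 TPM against 343 ± 51.5 for mt-Co2 itself (second 2779). The deposited TPM intervals did not hold these values. For mt-Co2 they were 1831 to 3299 in replicate 1 and 1595 to 3169 in replicate 2. For Gm28661 they were 13638 to 15122 in replicate 1 and 14469 to 16062 in replicate 2.

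Short non-coding RNAs held the highest nuclear values of the gene tables, beside the mitochondrial ribosomal RNAs mt-Rnr2 at 71140 ± 2605 TPM and mt-Rnr1 at 38325 ± 778. Rn7s1 and Rn7s2, 2 genes of the signal recognition particle RNA on chromosome 12 (69159295 to 69159594 and 69361182 to 69361481), had 95352 ± 2972 TPM each (second 0.651), a division of shared reads that cannot be checked from these tables. Rn7sk, which restrains the transcription elongation factor P-TEFb, reached 30843 ± 319 (second 0.300) and the RNase P RNA Rpph1 reached 7156 ± 801 (second 1.90). The 20 highest genes took 47.9% ± 1.01 of mouse-gene TPM but 27.3% of expected counts. Gm26917 on chromosome 17 (39843013 to 39846341), which the annotation types as a long non-coding RNA, reached 14230 ± 553. The source of the reads on Gm26917 was not tested. Malat1 reached 3271 with an SD of 1090 (second 1918).

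All 20 genes of the G2/M list and all 20 of the S phase list were expressed in both hearts. Top2a, which untangles replicated DNA, stood at 65.8 ± 10.1 TPM, Cdk1 at 47.7 ± 9.54 and Mki67 at 36.6 ± 5.35. The replication factor Pcna reached 70.8 ± 9.09 (second 131) and the histone gene Hist1h3b reached 242 ± 4.82 (second 525). Among cell cycle inhibitors, Cdkn2a and Cdkn2b had mean TPM of 0.095 and 0.34, while 8 of 10 were expressed, with Cdkn2c at 23.0 ± 3.73. The fetal growth factor Igf2 stood at 705 ± 21.3 and the imprinted RNA H19 at 507 ± 10.6.

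Markers of several heart cell types were present. All 12 fibroblast, 12 endothelial, 12 mural and 12 epicardial markers were expressed, at median TPM of 67.7, 41.4, 23.6 and 5.87. Fibroblast markers were led by Col3a1 at 580 ± 160 (second 909) and Col1a1 at 357 ± 68.0. The extracellular matrix list took 0.455% ± 0.0568 of mouse-gene TPM and 1.57% of expected counts. Of the endothelial markers, Fabp4 stood at 335 ± 7.77 and Cdh5 at 115 ± 8.77. Atrial markers Nppa and Myl7 were present at 1143 ± 675 and 651 ± 78.5 (second 1017 for Myl7). Of 12 conduction markers 8 were expressed, with Gjc1 at 35.3 ± 0.573. Macrophage markers were low, with 9 of 12 expressed and Lyz2 at 12.9 ± 3.93. None of 12 T cell and thymus markers reached a TPM of 1 in both hearts, and 1 of 8 B cell, 3 of 10 neutrophil and 4 of 7 mast cell markers did.

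**Figure D1:**
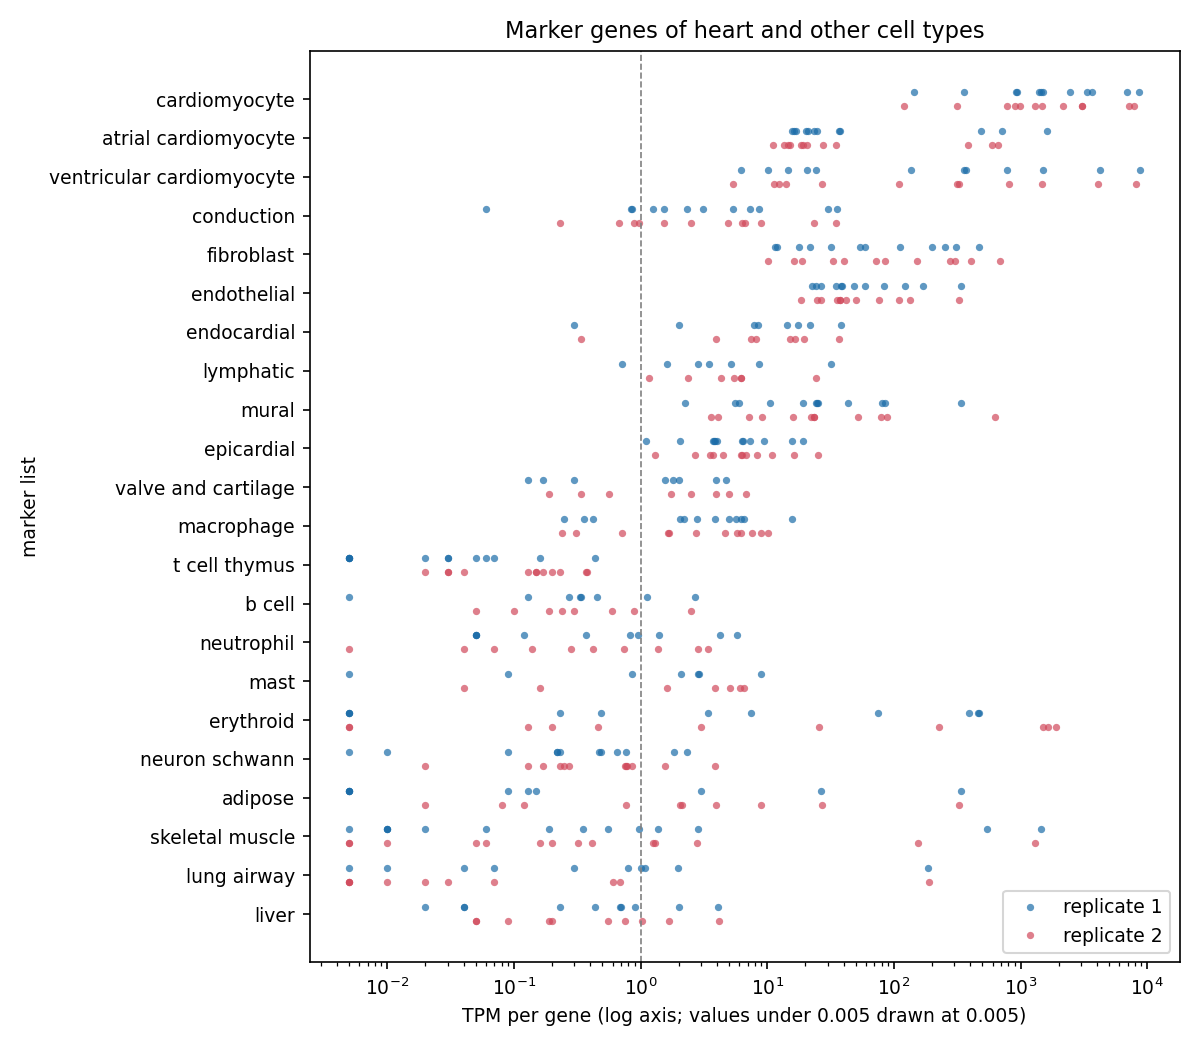
TPM of each marker gene on a log axis, by marker list, with 1 point per gene and heart (blue replicate 1, red replicate 2) and a dashed line at a TPM of 1. Cardiomyocyte markers sit highest, with a list median of 1437 TPM (second 2331), and all 12 T cell and thymus markers have mean TPM under 1.

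Markers of other tissues were near the detection limit with exceptions. Among liver markers, Ahsg had 4.11 ± 0.0354 TPM and Alb 1.84 ± 0.219, and 2 of 10 were expressed. The lung list was led by Hopx at 188 ± 2.61, a gene also transcribed in heart muscle, and the surfactant gene Sftpc had 1.29 ± 0.976. Its list median was higher in replicate 1, with a TPM of 0.55 against 0.025 in replicate 2. Of 14 skeletal muscle markers 4 were expressed, with Ckm (1375 ± 118; second 2279) and Acta1 (347 ± 271; second 704) being shared with the heart, while Myod1 was listed at 0. Of the interferon response genes 5 of 15 were expressed, and Ifit1 had a mean TPM of 0.08 (second 0.271).

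Partner genes were compared within each heart to ask which isoform gene predominated. The first-named partner, in most pairs the adult or muscle-type gene, was higher in both hearts in 26 of 30 pairs, the other partner in 3, and 1 pair was divided. The reported TPM intervals of the partners, some of which do not hold the TPM itself, did not overlap in either heart for 29 pairs. Myh6 exceeded Myh7, the slow myosin of the fetal ventricle, by a log2 ratio of 3.32 ± 0.22, or 9.96-fold (2.15, or 4.44-fold, by the second quantification). Cardiac troponin I Tnni3 exceeded the fetal form Tnni1 by 1.41 ± 0.33. Myl2 exceeded the atrial Myl7 by 3.70 ± 0.10 (4.37 by the second quantification). Atp2a2 exceeded Atp2a1, at a mean TPM of 0.33, by 12.46 ± 0.27, a ratio that fell to 10.81 with a pseudocount of 1 and was 13.06 by the second quantification. Cpt1b exceeded Cpt1a by 2.04 ± 0.21 and the insulin-responsive glucose transporter Slc2a4 exceeded Slc2a1 by 2.91 ± 0.33 (2.27 by the second quantification). Adult beta-globin Hbb-bs stood at 1179 TPM against 0.065 for the embryonic Hbb-y, and the log2 ratio rests on the pseudocount, with 12.60 at 0.1 and 9.79 at 1.

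The second partner was higher for Hk2 over Hk1 (log2 ratio -1.03 ± 0.35), Cox7a1 over Cox7a2 (-0.25 ± 0.04, and -1.29 by the second quantification) and Igf1 over Igf2 (-4.39 ± 0.05). Ldhb over Ldha was 0.34 ± 0.06, and 1.06 by the second quantification. Rbm20 over Rbm24 was 0.58 in replicate 1 and -0.01 in replicate 2. Actc1 over Acta1 was 3.69 in replicate 1 and 5.68 in replicate 2, with a mean of 4.68 that was 4.08 by the second quantification. Nppa over Nppb, both natriuretic peptides, was 3.41 in replicate 1 and 1.11 in replicate 2.

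**Figure D2:**
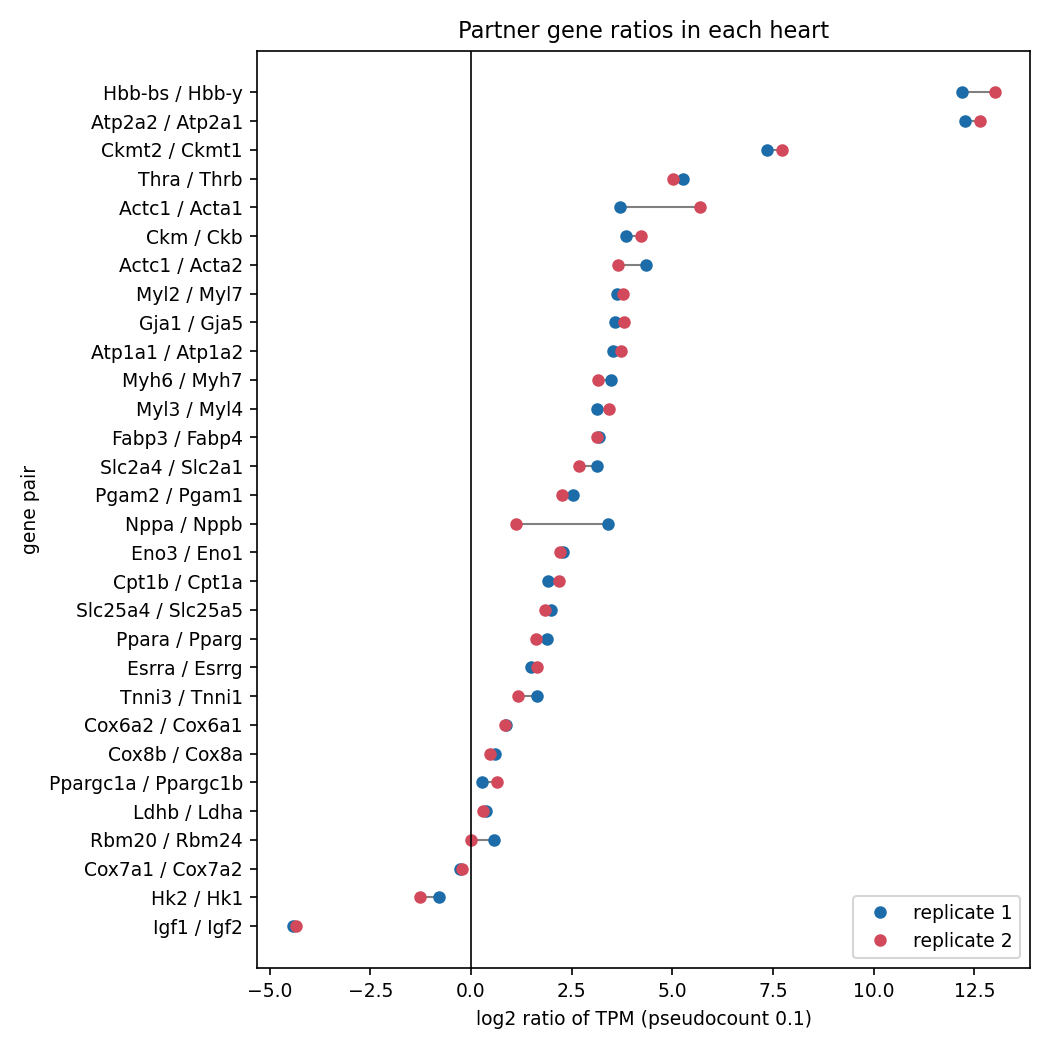
Log2 ratio of TPM for each of 30 gene pairs, with 1 point per heart (blue replicate 1, red replicate 2) joined by a line, and a vertical line at equal levels. In 26 pairs both points lie right of that line, and Nppa over Nppb moves from 3.41 to 1.11.

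Leading transcripts were examined for 30 genes known for regulated splicing. The leading transcript held a median of 45.0% ± 2.66 of a gene's TPM, and it was the same in both hearts for 25 genes. Actn2-201 held 97.3% ± 0.257 of Actn2, Tpm1-205 held 94.8% ± 0.0475 of Tpm1 and Slc25a3-206 held 85.0% ± 0.486 of Slc25a3. By the second quantification the same transcripts held 85.4% ± 9.66, 71.1% ± 1.19 and 69.8% ± 1.37, so the SD between hearts understates the error of these shares. Titin was divided among more forms, with Ttn-201 at 38.1% ± 0.385 and Ttn-215 at 28.9%. Pkm-201 and Pkm-202 were nearly equal at 48.3% ± 1.19 and 47.1%. The second quantification gave the same leading transcript for 23 of 30 genes. For Tnnt2 it put 0% on Tnnt2-207, which held 41.1% ± 4.35 in the first, and 57.9% on Tnnt2-209, so the leading Tnnt2 form is uncertain.

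The 2 hearts were next compared with each other to measure the error behind every value. The common biological coefficient of variation was 15.2%, and the median absolute log2 ratio over 16271 filtered genes was 0.19. Of these genes 498 differed over 2-fold, 137 higher and 361 lower in replicate 2, against 163 and 313 with spike-in scaling and 93 and 127 among nuclear protein-coding genes. Most of the 498 had low counts. Among the 12063 genes with a mean of at least 100 counts, 130 differed over 2-fold and the median absolute log2 ratio was 0.16. A chi-square per degree of freedom of 30.8 over 16390 genes shows that the libraries differed by far more than sampling noise and are not copies of a single library. Spike-ins took 0.588% of counts in replicate 1 (exact 95% interval 0.585 to 0.590) and 0.545% in replicate 2 (0.542 to 0.547). After TMM scaling, the 27 spike-ins with at least 100 counts had a median log2 ratio of -0.05. These differences have no replicate check and describe 1 heart against 1.

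Globin and heme genes were higher in replicate 2. Of the 42 lists, the erythroid list had the highest median, with a log2 ratio of 1.90 over 7 members, all 7 higher in replicate 2. Hbb-bs (chromosome 7, 103826534 to 103828096) had 471 TPM in replicate 1 and 1886 in replicate 2 (mean 1179, second 2469), and Alas2, the first enzyme of heme synthesis in red cells, had 7.44 and 25.7 (mean 16.6, second 25.9). The erythroid list took 0.142% and 0.534% of mouse-gene TPM in the 2 hearts, a mean of 0.338% that was 0.142% of expected counts and 0.626% by the second quantification.

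Fibroblast, matrix, G2/M and S phase genes were also higher in replicate 2. The fibroblast list had a median log2 ratio of 0.48, with 11 of 12 members higher, and the extracellular matrix list had 0.39, with 24 of 26 higher. Eln, which encodes elastin, had 262 TPM in replicate 1 and 474 in replicate 2. All 20 G2/M genes were higher, with a median of 0.56, and 15 of 20 S phase genes were, with a median of 0.24. All 4 lists lay at percentile 100 of the matched random lists. Replication histones did not pass the limits (0.08, 12 of 20 higher, percentile 73.8), and cell cycle inhibitors did (0.20, 6 of 8 higher, percentile 98.5). Epicardial (0.33), macrophage (0.29), valve and cartilage (0.59), lymphatic (0.54) and mast cell (0.97) lists lay at percentile 99.8 or above, and immediate early (0.15), thyroid and glucocorticoid (0.19) and neuron and Schwann (0.35) lists at 98.1 or above. The heart non-coding list had the lowest median, -0.24 at percentile 0 with 10 of 17 lower. The random lists were not matched on gene type, so this percentile can partly reflect type. Median log2 ratios were -0.10 for lincRNA (long non-coding RNA) and -0.20 for processed transcript genes, against 0.14 for snoRNA and 0.36 for snRNA genes. Sarcomere genes lay at percentile 0, with a median of -0.08 against 0.10 for matched random lists, glycolysis genes at percentile 0.01, with a median of -0.12, and general cardiomyocyte markers at 0.88, with a median of -0.05. The 20 bins hold equal numbers of genes, so the highest bin spans a wide range of levels. Lists of abundant genes, such as sarcomere, are matched on expression only loosely. The nuclear oxidative phosphorylation list lay at percentile 0.25, with a median of -0.03 that turned to 0.015 with spike-in scaling and to 0.015 by the second quantification. In all, 22 of 42 lists lay past the percentile limits, 16 above and 6 below, where 2.1 would be reached by chance if genes were independent. Lists share members, so this tally uses some genes more than once. Other lists held 6 of 12 fibroblast, 6 of 26 matrix, 14 of 26 sarcomere and 10 of 12 general cardiomyocyte genes.

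Single genes differed further. Ucp1, the heat-producing uncoupling protein of brown fat (chromosome 8, 83290352 to 83298452), had 0 counts in replicate 1 and 396 in replicate 2, at least 116-fold higher at the floor of 3 counts, which is a one-sided 95% limit, and at least 94.2-fold by the two-sided exact 95% interval. Car3 was 16.9-fold higher in replicate 2, the nuclear receptors Nr4a3 and Nr4a1 4.44-fold and 3.88-fold, and the insulin receptor substrate Irs2 3.69-fold. Lower in replicate 2 were Klhl38 (log2 ratio -2.55), Itgb6 (-1.73), skeletal actin Acta1 (-1.67) and the mitochondrial carrier Ucp3 (-1.57). Nppa had 1620 TPM in replicate 1 and 665 in replicate 2, and 9 of 12 atrial markers were lower, with a list median of -0.22 at percentile 0.04. Gm45837 had 377 counts in replicate 1 and 0 in replicate 2, but 1317 and 587 by the second quantification, so its difference is uncertain. The log2 ratios of Gm44502 and Chtf8 were -1.48 and -1.35 and turned to 0.12 and 1.58 by the second quantification.

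**Figure D3:**
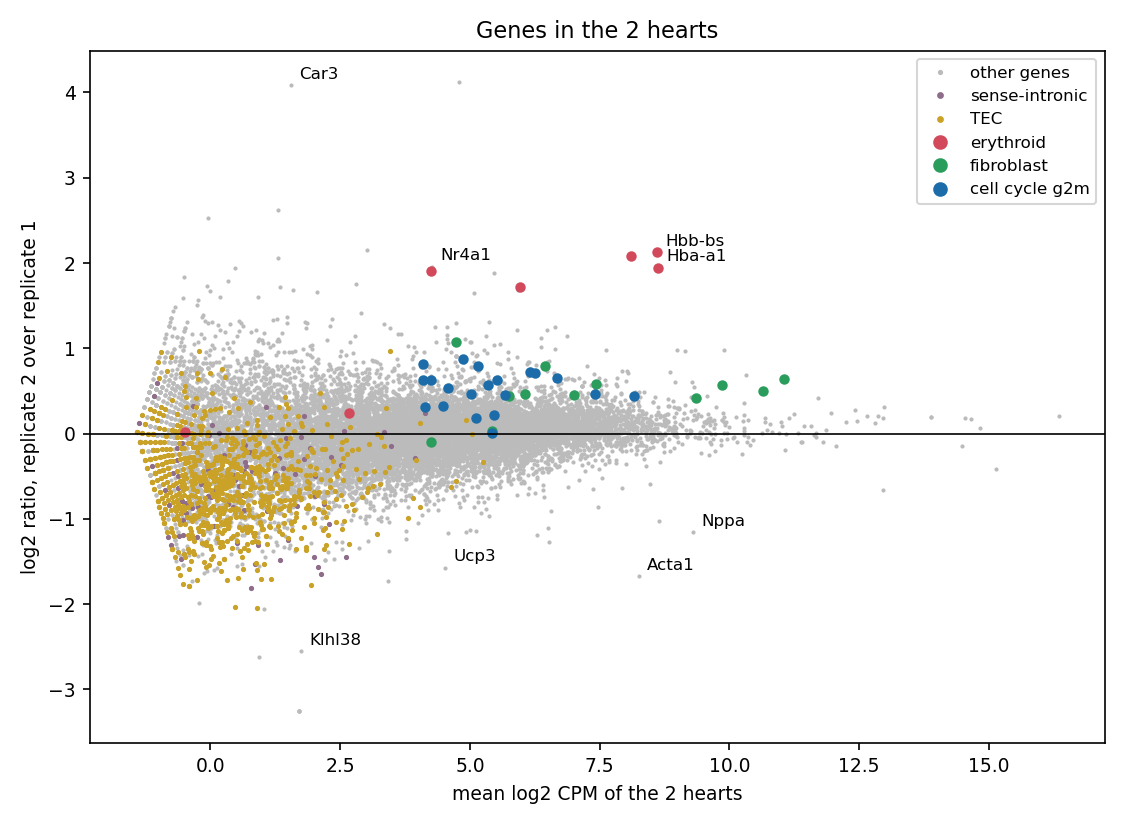
Log2 ratio of replicate 2 over replicate 1 against mean log2 CPM for 16271 filtered genes, 1 point per gene, with sense-intronic genes, TEC genes and 3 gene lists in colour and a line at 0. Erythroid genes lie high, with a list median of 1.90, and most TEC genes lie below 0, with a median of -0.58.

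Genes of intron-derived and unclassified types were lower in replicate 2. Sense-intronic genes had a median log2 ratio of -0.60 over 111 genes, of which 100 were lower, and TEC genes, which are loci awaiting experimental support, had -0.58 over 912 genes, of which 811 were lower. Protein-coding genes had a median of 0.02. TEC genes made up 166 of the 361 genes over 2-fold lower in replicate 2.

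The sex label was checked from sex-linked genes. Of 8 Y-linked genes 4 were expressed, with Eif2s3y at 38.5 ± 3.76 TPM, Ddx3y at 21.4 ± 2.04, Uty at 10.2 ± 1.75 (second 16.5) and Kdm5d at 6.97 ± 0.707, while Sry, Zfy1 and Zfy2 were listed at 0. Xist, which silences an X chromosome in females, had 4 and 6 counts.

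The 2 quantifications of the same libraries were compared last, since their difference is an error that replicates do not show. Of 15568 genes with a mean TPM of at least 1 in either, 1954 differed over 2-fold in the same direction in both hearts, 1347 higher and 607 lower in the second. The second values were higher by a median of 1.36-fold, and with the ratios centred on their median, a choice made after seeing the data, 1508 genes differed, 849 higher and 659 lower. Across 55450 genes, which are not independent replicates, Pearson's r of log2 TPM was 0.936 in replicate 1 and 0.940 in replicate 2. Genes without counts enter r, since in the first quantification 26298 genes had at least 1 count over both libraries. All 31 genes up to 300 nt with at least 1000 counts kept under 1% of them in the second quantification. Rn7s1 had 455311 counts in the first and 1.5 in the second in replicate 1. The 10 genes that differed most were all lower in the second and included Rn7s2, Rn7sk, Rmrp and mt-Atp8. Genes over 2000 nt had a median of 107.7% of the first count.

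**Figure D4:**
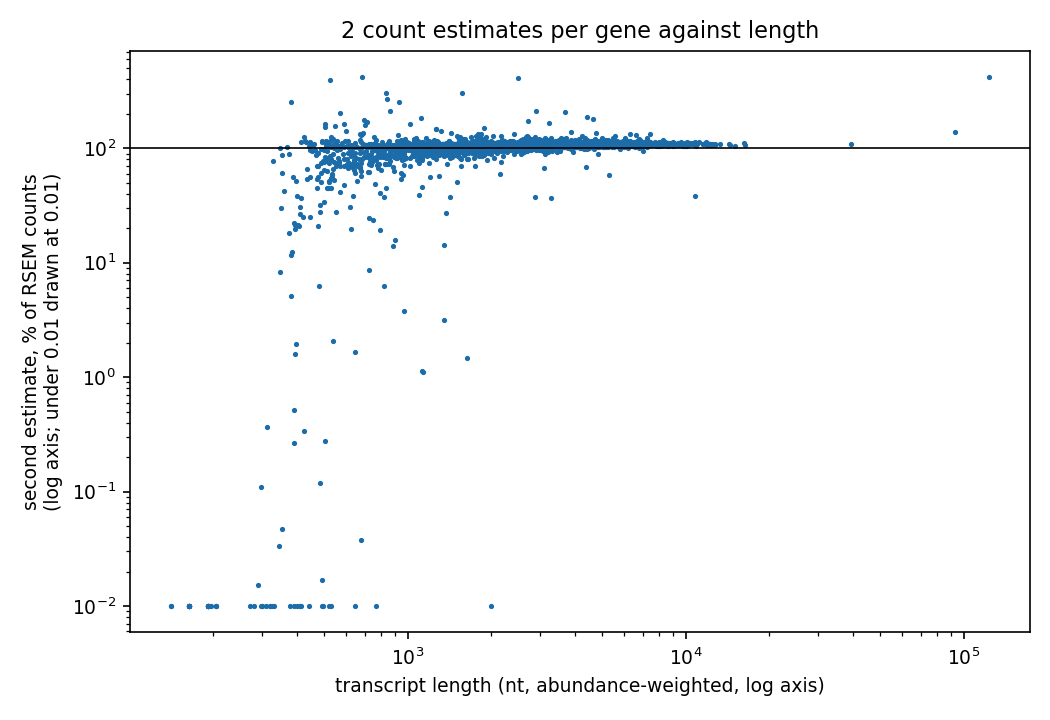
Counts by the second quantification as a percent of those in the first, on a log axis, against transcript length in nt on a log axis, for genes with a mean of at least 1000 counts, with a line at 100%. Genes up to 300 nt lie under 1%, and genes over 2000 nt have a median of 107.7%.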

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

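The numbered short rows of the gene tables, which name no mouse gene and entered no comparison, held 4 counts in replicate 2. They held 2 in replicate 1. Both are sums over 26248 rows, and the floor of 3 counts is set for a single count of 0, so it gives no limit for them. The share of these rows in the replicate 2 library was 1.11e-05%.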

How the results depend on the processing

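The number of expressed genes, the coefficient of variation, the 26 of 30 pairs, the Y-linked genes and the count of lists past the limits (20 to 25) stayed within 1.5 times of their values under all alternatives run for each. The duplicate check had no alternative. No paired analysis was possible because there is 1 group. Random lists from protein-coding genes and ratios centred on their median were chosen after seeing the data.

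Most shares moved by over 1 SD with the denominator. As a share of protein-coding TPM, mitochondrial genes took 14.7%, sarcomere 9.36%, oxidative phosphorylation 3.14%, matrix 0.872%, erythroid 0.654% and the protein-coding ones of the 20 highest genes 15.6%. Of expected counts the 6 took 5.89%, 9.57%, 1.34%, 1.57%, 0.142% and 27.3%; of these the erythroid share alone stayed within 1 SD. By the second quantification the 6 shares were 10.3%, 7.81%, 2.39%, 0.620%, 0.626% and 33.0%, the leading transcript share was 37.5% and the spike-in share 0.414%. Rn7s1, Rn7s2 and Rn7sk had mean TPM of 95352, 95352 and 30843 in the first quantification and 0.651, 0.651 and 0.300 in the second. TPM is scaled to a fixed total, so their loss raises the summed TPM of the other genes by construction. How much of each change this accounts for was not tested. All 48 list medians of TPM moved up by over 1 SD when rescaled to nuclear protein-coding genes, by construction of the smaller total.

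Of lists between hearts, nuclear oxidative phosphorylation changed sign with spike-in scaling (0.015) and the second quantification (0.015), staying past the percentile limit in both. The thyroid and glucocorticoid list (0.17, percentile 93.5) lost its place by the second quantification, and the neuron and Schwann list (0.35, percentile 97.4) against protein-coding random lists. Gm44502 and Chtf8 turned to 0.12 and 1.58 by the second quantification. The cause was not tested.

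Without a filter beyond 1 count, the median absolute log2 ratio was 0.31 and 2584 genes differed over 2-fold, since low counts enter; among nuclear protein-coding genes 220 (1.62%, against 3.06% of all) did, 93 higher and 127 lower, with TEC genes left out. Between quantifications, 947 genes differed at a mean TPM of at least 5, 4579 at 1.5-fold and 650 among protein-coding genes, by construction of those limits. Of 30 pair ratios, 19 moved by over 1 SD by the second quantification, 5 with a pseudocount of 1 and 3 with posterior mean TPM, and none of the 29 pairs with 1 direction in both hearts changed sign. Depth limits statements on genes at 0 to 0.0952 and 0.0839 CPM in replicates 1 and 2.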

Other observations

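Tests of the adipose genes and of the nuclear copies, and the genomic DNA test, were chosen only after the results were seen, except that limits for the further fat genes were set before their values were; those on retained introns and on length and level were written before, but repeating them with the second quantification was a later choice.

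Further genes differed between the hearts. The imprinted list had a median log2 ratio of 0.19 with 13 of 20 members higher in replicate 2, at percentile 99.5. Lower in replicate 2 were 3 members of the heart non-coding list, some imprinted too: Meg3 had 154 TPM in replicate 1 and 44.4 in replicate 2, Rian had 107 and 41.4, and Malat1 had 4042 and 2500. The clock list did not pass the limits, with a median of -0.04 at percentile 22.7 and 8 members on each side, Per3 at -1.13 and Dbp at -0.96 against Per1 at 0.74 and Nr1d1 at 0.44. Pdk4, which limits glucose oxidation, was lower in replicate 2 (-0.86). The natriuretic and stress list had a median of 0.67 at percentile 100, with 7 of 10 higher, among them Nppb at 1.14 and Ankrd1 at 0.98 against Nppa at -1.15. None of these has a replicate check.

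Some genes known from fat were higher in replicate 2. Beside Ucp1, Plin1 had 0 and 116 counts (8.04 and 123 by the second quantification), Adipoq 1 and 59, and Cidec 1 and 26. A further 23 fat genes outside the lists were taken from background knowledge, and 11 had a mean TPM under 2 and at least 10 counts over both hearts. Their median log2 ratio was 0.89, with 10 higher, at percentile 99.97 of random lists matched on counts, which is consistent with fat attached to that heart as a hypothesis. Fabp4, Cidea and Pparg, which both hearts expressed, hardly moved (0.05, 0.15 and 0.23). The depth of replicate 2, 1.13 times that of replicate 1, is far from the Ucp1 difference of at least 116-fold at the floor of 3 counts, or at least 94.2-fold by the two-sided exact interval. Other tissues were checked with 30 liver, lung, skeletal muscle and T cell genes under a TPM of 0.5 in replicate 1. That check could show only a rise in replicate 2. Only 1 gene had an exact interval of the ratio wholly above 2, Rag1 with 5 and 31 counts. Median TPM in replicates 1 and 2 was 0.565 and 0.375 for the liver list and 0.55 and 0.025 for the lung list. It was 0.27 and 0.26 for skeletal muscle, and 0.03 and 0.15 for T cell and thymus markers. Reads from a brown fat library of the same run would bring the same fat genes, so that source stays open.

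Intron-derived genes were lower in replicate 2, as given above. Against protein-coding genes of like length and level, sense-intronic and TEC genes still had a median of -0.57, and -0.44 by the second quantification, which argues against those properties as the whole cause. Retained-intron transcripts had a median log2 difference of -0.40 against protein-coding transcripts of the same gene over 4861 genes, 77.9% of them lower, and -0.41 by the second quantification, so a larger unspliced share in replicate 1 is a candidate explanation. Genomic DNA in replicate 1 would move these the same way and stays open, since 1503 chemosensory receptor genes gained per kb 0.590% of what sense-intronic genes gained in the first quantification but 21.6% in the second, between the limits of 10% and 50% set for the test. The receptor genes held 604 and 490 counts in replicates 1 and 2 in the first quantification, but 25954 and 17616 in the second. The 21.6% thus rests mostly on counts that the first quantification did not give to these genes. Whether the lower level of intron-derived genes in replicate 2 reflects handling of the tissue or the animal was not tested, as no biological explanation can be with 1 group.

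Of the 3 chromosome 1 copies of mitochondrial genes that were compared, counts on 1 depended strongly on the quantification. The pseudogene Gm29216 beside them (24615706 to 24616197) was not compared with a mitochondrial gene. In replicate 1 it had 72010 counts in the first quantification and 27.8 in the second. Gm10925, identical to mt-Atp6 over 678 nt, took 52.4% ± 4.12 of the pair's counts in the first and 0.0320% ± 0.00186 in the second, a move of 52.4 percentage points. Gm28661 took 98.1% ± 0.339 of its pair with mt-Co2 in the first and 90.1% ± 0.460 in the second, and Gm28437 took 55.7% ± 6.77 and 61.6% ± 0.472 of its pair with mt-Co3. Reads shared between identical genes could account for this, but the Gm10925 pair's total also differed 1.62 times between the quantifications, more than the limit of 1.5 set for sharing alone and than the 1.23 and 1.27 of the mt-Co2 and mt-Co3 pairs, so it stays open. Transcription of the copies cannot be told apart from that of the mitochondrial genes, as 0 bases of the 3 copies differ from the genes they match.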
